A study of Oryza sativa with 4 samples.

How the data were processed

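Small RNA from rice leaves (Oryza sativa) was sequenced in 4 libraries, 2 made with HD adapters and 2 with standard Illumina adapters. HD stands for high definition; these adapters carry random bases at the ends that are ligated to the RNA. Per the labels, the plants grew in chambers without a specific treatment, and total RNA was taken from leaf tissue. Groups and replicate numbers came from the sample titles and the adapter labels. The labels' protocol text names standard Illumina adapters for all 4 libraries, including both labelled HD, so the group names rest on the titles and the adapter labels, which give the same groups. The labels do not say whether the replicates, or the adapter groups, came from the same or separate plants or RNA. The p-values therefore measure only the spread between these libraries, which may be technical.

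The deposited values are raw read counts, 1 per distinct read sequence, with no normalization, as seen in the files, which have no header. The authors collapsed identical reads, and no sequence was repeated within a library. The shortest read was 17 nt in every library, and the longest was 33 nt in both HD libraries and 41 nt in both standard libraries. The genome build IRGSP-1.0 is named in the submitters' processing notes without a role. The adapter trimmer, the aligner and any filter on genome matches are not given in the sources used here. Read totals were 14130817 and 13815739 for HD replicates 1 and 2, and 12402786 and 10880546 for standard replicates 1 and 2. No molecular identifier is recorded, so reads are not independent molecules, and all counting intervals and floors cover counting error only. 

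Reads of 18 to 30 nt were analysed. They made up 12285122 and 12738621 reads in the HD libraries and 10546346 and 8642207 in the standard libraries, and CPM (a count divided by this total and scaled to a common depth) is relative to these totals. A count of 0 in a library allows up to 3 reads, which was 0.244 and 0.236 CPM in the HD libraries and 0.284 and 0.347 CPM in the standard libraries. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1, were used. Sequences were tested if they reached 10 reads per median library (0.876 CPM) in at least 2 libraries and 15 reads in all, which kept 66658 of 7581540 distinct sequences. Counts were scaled by the trimmed mean of M values (TMM; 30% trimmed by ratio and 5% by abundance). HD was compared with standard by limma voom with moderated variances, and Benjamini-Hochberg adjusted p under 0.05 counted as a call. Fold changes are HD over standard. A quasi-likelihood count test had been chosen before the data were examined. It was not run, because each deposited cell joins a sequence and its count and so did not meet the count-table format set for that test; limma voom took its place. A second count-model test planned as an alternative was not run for the same reason.

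A list of 50 mature miRNA and trans-acting siRNA sequences in 7 groups was written from memory of miRBase before the data were examined, and reads were counted by exact match to each sequence. A wrong base in a sequence recalled from memory would give the same result as absence. The groups were auxin, phase change, leaf development, nutrients and stress, small RNA machinery, monocot miRNAs, and reproductive miRNAs of panicle and anther. Members with the same sequence family can share sequence variants, and an exact match assigns a variant to no member. Groups were tested with camera (preset correlation 0.01, and estimated correlation) and fry. The sequences named were fixed by rule. In each group these were the 2 called members with the highest and the 2 with the lowest log2 fold change. The 3 listed miRNAs with the highest mean CPM over all 4 libraries and any reproductive miRNA were added. Outside the list they were the 2 highest and the 2 lowest log2 fold changes among called sequences with a mean CPM of at least 100. Sequences named beyond this rule are said to have been chosen after their values were seen.

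Shares of reads and numbers of distinct sequences were compared by two-sided exact permutation tests of 2 against 2 libraries, whose smallest possible p is 0.333. These cannot pass a threshold, so both values of each group are given. Distinct sequences at equal depth are the expected number after keeping reads at random down to the 8642207 reads of the smallest library. The test was checked on simulated counts for 66658 sequences at the real library sizes, of which 53361 passed the filter, with 50 sequences changed at each fold size. It called 6.00% of the 2-fold, 66.0% of the 4-fold, 94.0% of the 16-fold and 98.0% of the 64-fold changes with the right direction. There were 4 false calls among 53161 unchanged sequences. Nearly all simulated sequences were unchanged, whereas 32937 of the 66658 real sequences were called. The real TMM factors ran from 0.709 in HD replicate 2 to 1.42 in standard replicate 2. The simulated rates, including that of false calls, were not checked for differences this widespread and may not carry over to the real data.

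Alternatives changed the scaling (median-of-ratios size factors, or library totals only), the filter (10 reads over all libraries), the length range (20 to 24 nt), the replicates (each left out, or the replicate number as a block), the counting of miRNAs (all sequences with the same first 18 nt) and the definitions of the shares. A limma trend fit with a prior count of 2 was chosen after the data were seen. No rice genome was used here, so sequences have no coordinates and the origin of reads from ribosomal, transfer or organelle RNA was not analysed here.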

Results

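Small RNA libraries from rice leaves were made with HD adapters (2 libraries) and with standard Illumina adapters (2 libraries) to compare, side by side, the small RNA populations that each adapter type recovers. The HD libraries held 14130817 and 13815739 reads and the standard libraries 12402786 and 10880546. Reads of 18 to 30 nt, the range compared here, made up 86.9% and 92.2% of the HD reads and 85.0% and 79.4% of the standard reads.

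Mature miRNAs, the small RNAs that guide cleavage or silencing of target transcripts, were recovered far more often with HD adapters. Of 50 listed sequences, 35 were abundant enough to be tested. Of these, 29 were higher with HD adapters, 0 were lower and 6 had no call (limma voom, Benjamini-Hochberg adjusted over all sequences tested). Adjusted over the list alone, 31 were higher and 0 were lower, and at an unadjusted p under 0.05 limma voom and limma trend each gave 0 that were lower. The 0 depended on TMM scaling: on library totals, limma voom gave 3 that were lower at an unadjusted p under 0.05, and 2 after adjustment over all sequences. CPM was higher in both HD libraries than in both standard libraries for 31 of the 35. It was lower in both for miR166a, miR396a and miR444b.1. Chance gives 16.7% for 1 miRNA, but all 35 come from the same 4 libraries, so they are not independent cases. The median ratio of mean CPM over the 34 with reads in both groups was 16.2. These values are for the exact listed sequences. When all sequences with the same first 18 nt were summed, the fold was over 1.5 times lower for 26 of the 35, and the sums ran from -1.12 to 5.44 on the log2 scale. The listed sequences took 2.06% and 2.44% of the HD reads but 0.384% and 0.273% of the standard reads, a mean of 2.25% ± 0.264 (SD, n = 2) against 0.328% ± 0.0785 (SD, n = 2). An exact permutation test of 2 against 2 libraries gave p = 0.333, the smallest it can give.

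All 5 tested members of the auxin group were higher in HD, with a median log2 fold change of 6.34 by exact match. miR160a, which targets repressive auxin response factors, had 55.9 ± 14.7 CPM in HD (SD, n = 2) and a single read in the standard libraries. Its log2 fold change was 10.18 ± 0.78 (SE), adjusted p = 0.00126, and the ratio of pooled shares was 1069 with a 95% counting interval of 192 to 42251. Summed by its first 18 nt, with 1118 and 864 reads in HD and 334 and 315 in standard, the log2 fold change was 2.15 (adjusted p = 0.012). miR167a, which targets activating auxin response factors, had 132 ± 5.12 CPM in HD against 0.953 ± 0.530 in standard, a log2 fold change of 8.05 ± 0.54 (SE), and the start it shares with miR167d gave 5.44 when summed. The lowest in the group were miR390, the trigger of trans-acting siRNAs against auxin response factors, at 4.96 ± 0.54 (SE), and miR393a, which targets auxin receptors, at 3.596 ± 0.409 (SE), and their sums were 4.28 and, for the start that miR393a shares with miR393b, 1.79. The 3 members below the filter each had at most 4 reads in the HD libraries together. They included both trans-acting siRNA sequences.

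Among the miRNAs of phase change, 3 of 4 tested members were higher in HD. miR156a, which targets SPL transcription factors and was the most abundant listed miRNA, reached 8811 and 10747 CPM in HD and 2115 and 1379 CPM in standard, a log2 fold change of 3.44 ± 0.44 (SE; adjusted p = 0.00605). miR172a, which targets AP2-like flowering repressors, had 28.2 ± 12.3 CPM in HD (SD, n = 2) and no read of the exact sequence in either standard library, at least 179-fold higher against a floor of 3 reads over both libraries. Other sequences with its start had 11 and 15 reads in standard, and the summed log2 fold change was 5.42. miR529b, which also targets SPL genes, had 70 reads in HD and 2 in standard, a ratio of 26.8 with a counting interval of 7.16 to 226, and its summed log2 fold change was 2.32. miR535 had no call (adjusted p = 0.0575), at 388 ± 10.2 CPM in HD and 316 ± 73.8 CPM in standard. It passed adjusted over the list alone (0.0348), with median-of-ratios factors (0.0393) and with limma trend (0.0466). On library totals it did not pass, with a log2 fold change of 0.31 (limma voom, adjusted p = 0.506) against 1.25 with TMM.

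Of the miRNAs of leaf development, 8 of 10 tested members were higher in HD. miR166k, of a family that targets class III homeodomain leucine zipper genes, had 71.6 ± 14.0 CPM against 1.12 ± 0.433 CPM (log2 fold change 6.89 ± 0.50, SE), and miR159a, which targets GAMYB genes, had 1660 ± 92.3 CPM against 35.7 ± 18.1 CPM (6.57 ± 0.53, SE). Summed by the first 18 nt these were 2.08 (adjusted p = 0.0145) and 3.46, and 85.4% and 84.1% of the standard reads with the miR166k start were shortened forms. The smallest called differences were those of miR394, at 3.47 ± 0.45 (SE), and miR166e, at 2.53 ± 0.39 (SE). The sum for miR394 was 2.39, and the start that miR166e shares with miR166a gave a log2 fold change of -1.12 (adjusted p = 0.0687). The members without a call were miR166a, with 153 and 200 CPM in HD and 359 and 351 CPM in standard, and miR396a, with 5.21 and 8.01 CPM in HD and 17.9 and 23.1 CPM in standard. The start that miR396a shares with miR396c gave a summed log2 fold change of 2.56 (adjusted p = 0.0117).

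The nutrient and stress miRNAs gave 7 of 8 tested members higher in HD, with log2 fold changes of 4.27 to 8.81. miR169b and miR169a, which target NF-YA transcription factors, were highest. miR169b had 537 reads in HD and 1 in standard, a ratio of 412 with a counting interval of 73.6 to 16294, and miR169a had 46.1 ± 15.5 CPM against 0.763 ± 0.261 CPM. The start they share had 59 and 29 reads in standard and a summed log2 fold change of 5.08. miR528, a monocot miRNA of copper and stress responses, had 1318 and 2111 CPM in HD and 115 and 91.3 CPM in standard (4.96 ± 0.44, SE; adjusted p = 0.00197), and 4.01 when summed. miR397a, which targets laccases, and miR398b, which targets copper/zinc superoxide dismutases, had log2 fold changes of 4.78 ± 0.48 (SE) and 4.27 ± 0.46 (SE), with a sum of 3.55 for miR397a. miR827, with 56 reads in HD and 3 in standard, had no call over all sequences (adjusted p = 0.0654). It passed adjusted over the list alone (0.0401), when summed by its first 18 nt (0.0228), with limma trend (0.00485), with a filter of 10 reads (0.0218) and without either HD replicate. It did not pass with median-of-ratios factors (0.07), on library totals (0.0614), at 20 to 24 nt (0.0765) or without standard replicate 1 (0.154) or 2 (0.139).

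Both miRNAs of the small RNA machinery were higher in HD. miR162a, which targets Dicer-like 1, had 928 and 918 CPM in HD against 60.2 and 75.2 CPM in standard (log2 fold change 4.71 ± 0.34, SE). miR168a, which targets Argonaute 1, had 2637 and 4073 CPM against 470 and 271 CPM (4.13 ± 0.51, SE). Their sums by the first 18 nt were 3.99 and 3.13. Of the monocot miRNAs, 4 of 6 tested members were higher. miR1425 had 1463 ± 253 CPM against 41.3 ± 8.50 CPM (6.08 ± 0.39, SE), and miR444a, of a family that targets MADS-box genes, had 612 ± 229 CPM against 37.0 ± 16.4 CPM (4.999 ± 0.544, SE). miR1876, a miRNA of 24 nt, was 4.18 ± 0.38 (SE) higher on the log2 scale, and miR1432 was 2.37 ± 0.34 (SE) higher. The sums for miR1425 and miR1876 were 3.76 and 3.42. miR444b.1 had no call, with 20.5 and 13.5 CPM in HD and 39.0 and 41.5 CPM in standard, nor did miR820a, with 24.8 ± 5.86 CPM and 22.4 ± 4.11 CPM, although its start passed when summed (2.15, adjusted p = 0.0158). The reproductive miRNAs, markers of panicle and anther rather than leaf, were near or under the detection floor. miR2118a had no read in any library, and miR2275a had 2 reads in each HD library and none in the standard libraries. The 6 members without a call fall outside the rule for naming and were named after their values were seen.

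With a preset correlation, camera placed the auxin (adjusted p = 0.012), leaf (0.0173), nutrient (0.00777) and phase (0.0255) groups above the other sequences, but not the machinery (0.080) and monocot (0.0545) groups. None held with an estimated correlation: each of the 6 groups had adjusted p = 0.221 with an estimated correlation. fry, which asks whether members move one way on balance, gave adjusted p of 0.00281 or less for each group. On library totals in place of TMM, 29 listed miRNAs were higher in HD and 2, miR396a and miR444b.1, were lower.

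**Figure D1:**
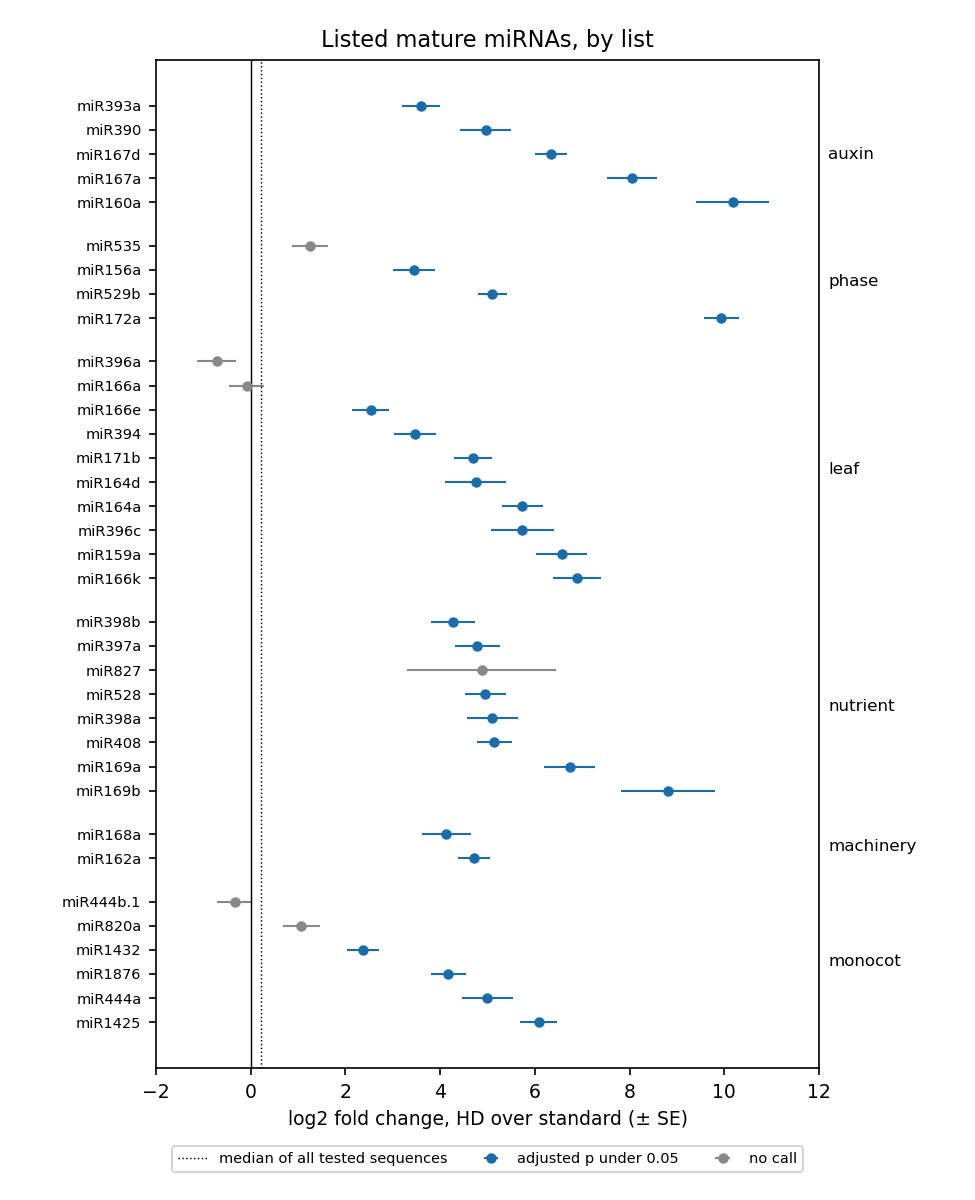
Log2 fold change (HD over standard, x axis) of the 35 tested listed miRNAs, one row each, sorted within their group; points are limma voom estimates from 2 libraries per group and bars are standard errors. Blue points passed an adjusted p of 0.05 (29 miRNAs, all to the right of 0), grey points did not (6 miRNAs), and the dotted line is the median of all tested sequences, 0.21; without TMM scaling the values lie 0.93 lower, and 2 grey points, miR396a and miR444b.1, pass as lower in HD.

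Over all sequences, differences between the adapters were common and ran in both directions. Of 66658 sequences, 22051 were higher and 10886 lower in HD (limma voom, adjusted p under 0.05), so that 66.9% of the calls were higher. On library totals only, 19134 were higher and 22317 lower (46.2% higher), since TMM moved the median log2 fold change from -0.72 to 0.21, a shift of 0.93; all directions here are relative to that scaling. No read in either standard library was found for 8061 of the sequences called higher, and no read in either HD library for 1847 of those called lower. These were all the tested sequences without reads in a group. The filter kept them only if both libraries of the other group reached it, so their direction was set by the filter and their number is no separate support. Sequences found in both libraries of a pair held 77.2% and 80.9% of the reads for the HD pair and 82.2% and 84.2% for the standard pair. Between adapter types they held 63.95% to 68.2% of the HD reads and 71.1% to 76.3% of the standard reads. Of the 100 most abundant sequences, 80 were shared by the HD libraries and 86 by the standard libraries, but 37 to 48 by libraries of different adapters. The counts of calls depended on single libraries. Without standard replicate 1 or 2, limma voom called 0 sequences (31072 and 47138 had an unadjusted p under 0.05), while limma trend called 26404 and 1435 (28 and 0 listed miRNAs). Without HD replicate 1 or 2, limma trend called 15972 and 16808 (15 listed miRNAs each), against 42904 (31) with all libraries.

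The sequences with the most extreme fold changes outside the miRNA list belonged to a single family with 2 different ends. TGTAAGGAAGCTGAAGCG, with 938 and 3693 CPM in HD and no read in standard, was at least 14972-fold higher in HD, and GGATGTAAGGAAGCTGAAGCG, with 1078 and 2726 CPM, was at least 12260-fold higher. TGTAAGGAAGCTGAAGCGGAAA, with no read in HD and 23081 ± 6309 CPM in standard (SD, n = 2), was at least 196220-fold lower in HD, and TAAGGAAGCTGAAGCGGAAA, with 11024 ± 3367 CPM in standard, was at least 93926-fold lower. All 4 had adjusted p = 0.00093 (limma voom), and none was matched to a genome here. TTGACAGAAGAGAGTGAGCAC, which is miR156a with 1 more base at the 5′ end and was chosen after its values were seen, had 40753 ± 3145 CPM in HD and 2331 ± 1177 CPM in standard, a log2 fold change of 5.16 ± 0.55 (SE; adjusted p = 0.00341).

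The 24 nt class, the size of siRNAs that direct DNA methylation, was the class with the greatest difference. Reads of 24 nt made up 23.7% and 22.3% of the HD libraries and 11.5% and 10.7% of the standard libraries (exact permutation p = 0.333, the smallest possible). Of distinct sequences, 42.6% and 42.2% were 24 nt in HD against 16.3% and 16.1% in standard. In the test of single sequences, 10879 of 17514 sequences of 24 nt (62.1%) were higher in HD and 1320 were lower. The median log2 fold change was 4.07, or 2.84 on library totals with sequences lacking reads in a group set at a floor of 3 reads. Of the 17514, 4489 (25.6%) had no read in either standard library. The filter kept these only through both HD libraries, and all of them were called higher. At every other length from 18 to 30 nt, 9.97% to 28.7% of the sequences were higher. Among 24 nt sequences, 72.1% of those that start with A, the base favoured by Argonautes of the AGO4 type, and 64.8% of those that start with G were higher in HD, against 35.7% with C and 37.1% with T. On library totals the median of the last 2 classes lay below 0, at -0.46 and -0.44.

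The 21 nt class, the size of most miRNAs, made up 14.2% and 16.6% of the HD reads and 12.1% and 11.9% of the standard reads. The direction depended on the measure: of distinct sequences, 7.43% and 8.01% were 21 nt in HD and 12.6% and 11.8% in standard. Of the 7577 tested sequences of 21 nt, 2158 were higher and 1305 lower in HD, but 1776 were higher and 2747 lower on library totals. Of the 6674 of 22 nt, 1883 were higher and 1278 lower, but 1608 and 2579 on library totals. HD replicate 2 held fewer long reads than HD replicate 1, with 0.981% against 5.21% of its reads at 30 nt.

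**Figure D2:**
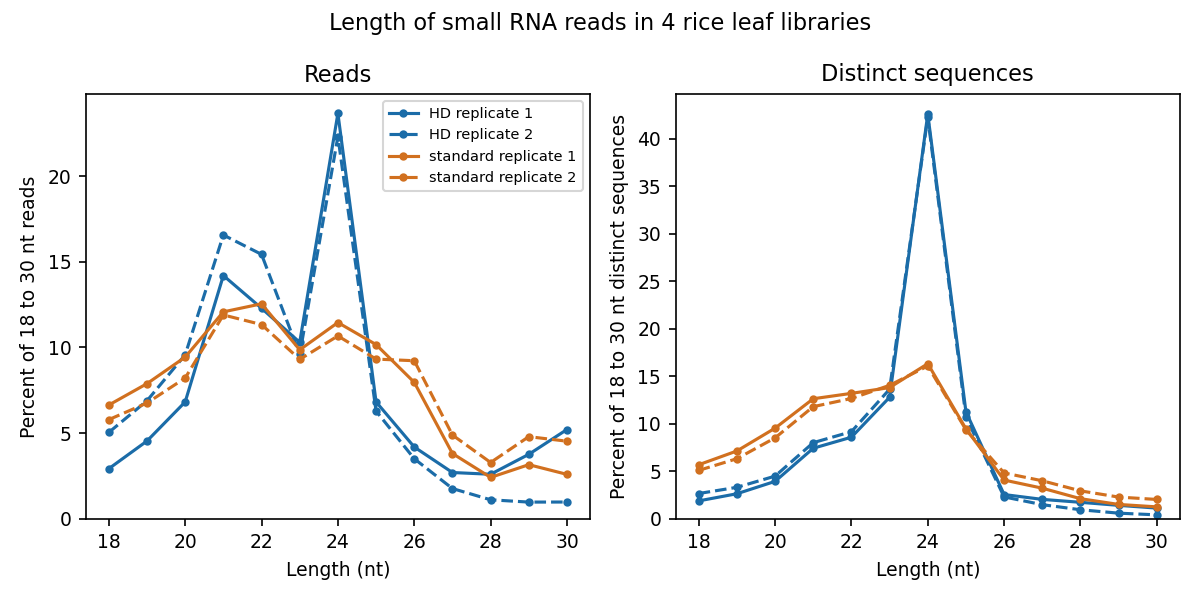
Read length in nt (x axis) against the percent of 18 to 30 nt reads (left) and of distinct 18 to 30 nt sequences (right), one line per library, HD in blue and standard in orange, replicate 1 solid and replicate 2 dashed. At 24 nt the HD libraries reach 23.7% and 22.3% of reads and the standard libraries 11.5% and 10.7%.

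HD libraries held more distinct sequences. At an equal depth of 8642207 reads, 2327619 and 2018086 distinct sequences were expected in the HD libraries and 1543702 and 1447440 in the standard libraries (exact permutation p = 0.333, the smallest possible). Counting only sequences with 2 or more reads at that depth, the values overlapped, at 418624 and 399626 in HD and 421916 and 394124 in standard. The 100 most abundant sequences took 33.7% and 39.8% of the HD reads and 34.7% and 34.6% of the standard reads, which overlapped (exact permutation p = 1). The 10 most abundant took 18.2% and 25.3% in HD and 13.4% and 13.2% in standard.

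The bases at the ends of the reads, where the adapters are joined, differed as well. Reads ending in A made up 26.4% and 24.4% of the HD libraries and 35.0% and 34.3% of the standard libraries (exact permutation p = 0.333), though of distinct sequences the share was higher in HD, at 31.5% and 30.6% against 25.1% and 26.4%. A large part of the difference in reads came from 1 family, which ended in GAAGCGGAAA in standard and in GAAGCG in HD. It took 7.71% and 5.02% of the standard reads and 0.350% and 1.05% of the HD reads. Reads ending in T made up 14.2% and 11.7% in HD and 21.1% and 21.1% in standard, those ending in C 40.3% and 46.0% against 31.03% and 32.35%, and those ending in G 19.1% and 17.9% against 12.9% and 12.3%. Of distinct sequences the share ending in C was lower in HD, at 25.8% and 27.2% against 28.9% and 29.5%, and at 24 nt it overlapped, at 30.3% and 33.8% of reads against 31.9% and 35.1%. The share ending in T overlapped at 24 nt too, at 16.7% and 14.8% against 15.9% and 15.9%. At the first base, A took 29.3% and 29.97% of HD reads and 25.0% and 23.7% of standard reads, and T took 25.6% and 25.3% against 32.98% and 29.94%. Within the 21 nt reads, T at the first base, typical of small RNAs bound by Argonaute 1, was commoner in HD, at 62.0% and 60.1% against 38.7% and 36.0%. The median log2 fold change of tested sequences was 1.62 for those starting with A, 0.44 with G, -0.54 with C and -0.62 with T. On library totals the value for G was -0.49. The values for A and G rested on the 24 nt class, where the medians were 4.605 and 4.502. They were -0.032 and -0.205 at 21 nt, and 0.225 and -0.004 at 22 nt. By last base it was 1.14 for G, 0.51 for A, -0.08 for C and -0.75 for T, with A at -0.42 on library totals.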

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

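Of the tests on the 3 patterns weighed here, those of differing ends, dilution, size selection and first base were chosen only after the result was seen. Reads outside 18 to 30 nt entered no comparison, and they exceeded in each library the share that a count of 0 allows. Reads of 17 nt made up 2.67% and 5.70% of all reads in HD replicates 1 and 2 and 7.84% and 7.58% in standard replicates 1 and 2. Reads of 31 to 33 nt made up 10.4% and 2.09% in HD and 6.13% and 10.2% in standard, so the spread within HD was as wide as that between the adapters. Reads of 34 to 41 nt occurred only in the standard libraries, at 0.992% and 2.80%, and the longest HD read was 33 nt.

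The first pattern is the higher recovery of listed miRNAs with HD adapters. Differing 3′ ends among reads of 18 to 30 nt do not account for all of it. Over the 30 distinct 18 nt starts, the median log2 fold change was 4.83 by exact match. It was 3.44 when all sequences with the same start were summed, against a median of 0.21 for all sequences in that fit. The median SE of the listed miRNAs was 0.44. Differing 5′ ends and forms shorter than 18 nt do not enter these sums and were not tested. The starts were also chosen through the exact form, which for some passed the filter through HD only. A single dilution of the standard libraries by other RNA would move all miRNAs alike. By exact match their log2 fold changes ran from -0.72 to 10.18 with an SD of 2.56. Differing 3′ ends widen this range, and the 10.18 is that of miR160a, with 1 read in standard. The sums by the first 18 nt still ran from -1.12 to 5.44, so dilution may be part of the difference but not the whole of it. Amplification copies of a few molecules cannot be told apart, since the numbers of distinct sequences per start at equal depth overlapped between the groups and only 5 of the 30 starts had more in both HD libraries. A difference in the RNA used for the 2 groups, which the labels leave open, was not tested.

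The second pattern is the family of sequences that ended in GAAGCG in HD and 4 bases later, in GAAGCGGAAA, in the standard libraries. In HD, 99.9% of the family's reads in each library ended in GAAGCG, and in the standard libraries 99.8% in each ended in GAAGCGGAAA. A loss of 4 bases from all HD reads is argued against, since the commonest length was 4 nt shorter in HD in only 5.57% of the 359 families that share their first 17 nt and were common in both groups, and equal in 59.6%. Of the 20 families that were 4 nt shorter in HD, 8 held the stretch that defines this family. Another 15 families were 4 nt longer in HD. What stays open is a ligation preference for 1 of the ends or a different RNA in the 2 groups. A trimming step that acted on part of the reads, this sequence among them, stays open too. No biological explanation was tested.

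The third pattern is the higher share of 24 nt reads in HD. Size selection around 24 nt would carry the neighbouring lengths along. But the share of 25 nt reads was lower in HD by 3.19 percentage points on average (-3.19, HD minus standard) and was lower in both libraries. At 23 nt the shares overlapped, at 10.3% and 9.59% in HD and 9.86% and 9.30% in standard. A cut of longer reads in HD would lower the 25 nt share too and stays open, so these values argue only against a selection around 24 nt. Of distinct sequences, however, 25 nt took 11.3% and 10.7% in HD against 9.47% and 9.37% in standard, so the argument holds for reads only. A few abundant sequences did not account for it: without the 100 most abundant sequences of each library the difference was 19.9 percentage points rather than 11.9. A preference for 1 first base is argued against, since 24 nt reads with each of the 4 first bases took a larger share in both HD libraries, with ratios of means from 1.25 for C to 3.19 for A. For C and T this holds for reads only. On library totals the median log2 fold change of tested 24 nt sequences was -0.46 for C and -0.44 for T, against 3.67 for A and 3.57 for G. A preference for A and G that is alike at 21, 22 and 24 nt is argued against too. The median log2 fold change of tested sequences with A and G minus that with C and T was compared. It was 4.07 at 24 nt but -0.05 at 21 nt and 0.56 at 22 nt, and other lengths were not compared. At 24 nt, 29.7% of the tested sequences with A and 31.2% with G had no standard read, against 11.9% with C and 9.08% with T. The filter kept these through HD only, so the size of the 4.07 rests in part on the filter. The RNA used for each group stays open as an untested cause.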

How the results depend on the processing

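The limma trend fit, the set tests on library totals and at 20 to 24 nt, and the values without the GAAGCG family were chosen after the data were seen; the other settings were fixed before the data were examined. The count of called sequences (32937) stayed within 1.5 times under median-of-ratios factors, library totals, 20 to 24 nt, limma trend and the replicate block. With the filter of 10 reads over all libraries it was 85275 of 200409 tested. With each replicate left out it ran from 0 to 36695, and for the listed miRNAs (29 called) from 0 to 30. The 0 calls came without standard replicate 1 or 2. The spread of the lone standard library was then assumed to equal that of the HD pair, and adjusted over the list alone 27 and 29 miRNAs were called; 29 had an unadjusted p under 0.05 in each case, and limma trend called 28 and 0. Without HD replicate 1 or 2 limma trend called 15 listed miRNAs each (31 with all libraries), and limma voom took the spread as equal for all sequences, so its high counts do not show that the HD replicates matter little. Library totals turned the share of calls higher in HD from 66.9% to 46.2%. The set tests called 4 groups, and 0 with an estimated correlation. For distinct sequences (677282 more in HD) the difference was 1306228 without thinning, 1105 for 2 or more reads, 356517 at 20 to 24 nt, and 522515 to 832048 with a replicate left out. For the 100 most abundant sequences (2.13 percentage points) it was 8.41 for 10 sequences, -2.61 for 1000, 5.22 at 20 to 24 nt, and -0.946 to 5.20 with a replicate left out, so HD replicate 2 decided its sign. The 21 nt difference (3.39) became -4.50 for distinct sequences and -0.644 within 20 to 24 nt, and ran from 2.21 to 4.57 with a replicate left out. The 24 nt difference (11.9) was 26.2 for distinct sequences, 12.05 within 20 to 24 nt and 11.24 to 12.6 with a replicate left out. The miRNA share (1.92) was 2.34 by the first 18 nt, 2.58 of 20 to 24 nt reads, and 1.74 to 2.11 with a replicate left out. Reads ending in A (-9.26) became 5.26 for distinct sequences, -10.9 at 21 nt and -3.05 at 24 nt, and ran from -10.3 to -8.26 with a replicate left out. For other bases, the sign turned at first base A at 21 nt (-7.62), C for distinct sequences, 21 nt and 24 nt (-2.39, -5.62, -5.52), G for distinct sequences (5.26) and, in a range of -3.96 to 0.633, with HD replicate 2 left out, and T at 21 nt (23.7), and at last base C for distinct sequences and 24 nt (-2.74, -1.44). The last base T difference (-8.11) fell to -0.144 at 24 nt. Summed by the first 18 nt, miR166e turned to -1.12 and miR396a, whose start is shared with miR396c, to 2.56. The cause of these changes was not tested, except that without a standard library only the HD pair measures the spread. Replicate numbers are shared between the groups, but nothing in the labels says that they pair libraries, and the deviations of same-numbered libraries correlated at 0.037. With the replicate number as a block, 39519 sequences and 31 listed miRNAs (miR535 and miR827 added) were called and the same 4 groups passed camera. The DESeq2 Wald test and the origin of the reads were planned and not run. Of the 15 listed sequences under the filter, miR159f, with 14 reads in HD and 0 in standard (at least 3.58-fold higher), was called with the filter of 10 reads (adjusted p = 0.00353). The low counts of the other 14 leave low abundance and a wrong base in the list open.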

Other observations

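The values in this part were chosen only after the results were seen. Among reads with the start of a tested miRNA, the exact listed form took a larger share in the HD libraries for most starts. Reads with another 5′ end did not enter these shares. For miR156a, the form with 1 more 5′ base had 1020790 reads in HD and 46311 in standard, against 245139 and 34222 of the exact form. The starts were also chosen through the exact form, which for some, such as miR172a, passed the filter through HD only. Among reads that begin with the first 18 nt of a tested miRNA, the median share of reads with the exact listed sequence over 30 such starts was 86.4% and 85.6% in HD and 37.9% and 33.9% in standard. The share was higher in both HD libraries for 28 starts and lower in both for 2, those of miR820a and miR444b.1. Some of the 28 had few standard reads, such as miR827 with 6 and 1 and miR397a with 17 and 4. For miR535 the groups nearly met, at 87.87% in HD replicate 2 and 87.72% in standard replicate 1. For 1 start, chance puts 2 libraries above the other 2 in 16.7% of cases, but all starts come from the same 4 libraries and are not independent. The listed form of miR159a made up 79.7% ± 0.220 of such reads in HD (SD, n = 2) and 9.94% ± 5.32 in standard, and that of miR1425 made up 89.2% ± 0.819 and 17.8% ± 3.29. For miR166a and miR166e, which share a start, the exact forms made up 76.7% ± 1.72 in HD and 34.9% ± 1.40 in standard, where the commonest sequence was 19 nt long. The 24 nt miR1876 followed, at 88.4% ± 0.590 and 52.0% ± 3.22. miR535 had no call in the main fit or on library totals but passed with median-of-ratios factors and limma trend. It was read in its listed form at 88.9% ± 1.48 in HD and 87.3% ± 0.603 in standard.

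The shares of the exact and other forms of a start add to 100%, so the other forms were compared by CPM. Reads cut short at the 3′ end had a lower CPM in both standard libraries for 20 of the 30 starts and a higher one for 5. For miR159a they had 229 and 262 CPM in HD and 83.3 and 68.3 CPM in standard, but for the start of miR166a and miR166e 30.2 and 49.8 CPM against 610 and 645 CPM. Reads with 2 or more added T bases had a higher CPM in both standard libraries for 15 starts and a lower one for 2, with sums over the starts of 88.5 and 76.9 CPM in HD and 259 and 292 CPM in standard. For miR159a these were 20.02 and 16.5 CPM in HD and 83.7 and 103 CPM in standard. The remaining forms had a lower CPM in both standard libraries for 14 starts and a higher one for 8. Their sums over the starts were 5481 and 6221 CPM in HD and 1923 and 2040 CPM in standard. Most of the HD sums came from the start of miR167a and miR167d and that of miR168a, and the higher sums in HD rest on these. The former had 2755 and 2526 CPM in HD against 117 and 91.8 in standard, and the latter 1707 and 2538 against 617 and 644. The medians of the remaining forms overlapped, at 8.79 and 6.40 CPM in HD and 6.31 and 6.42 CPM in standard. No explanation of these forms was tested.

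Outside the GAAGCG family, the last 4 bases GCCT ended 0.158% and 0.159% of distinct sequences in HD and 1.62% and 1.63% in standard, the lowest ratio of HD to standard among the 256 combinations. The last 4 bases TCCA had the highest ratio, at 0.514% and 0.501% in HD against 0.174% and 0.190% in standard.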
